A study of Sorghum bicolor with 14 samples.

How the data were processed

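RNA was sequenced from the middle stem internode of sweet sorghum variety ICSV12012, in 14 libraries of 7 groups, 4 of development stages and 3 of soil moisture. Per the labels' protocols the RNA was total RNA and the libraries were made with a stranded total RNA kit. Groups were taken from the stage or condition each label states, with 2 libraries in each.

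The deposited values are FPKM, which per the file headers the authors gave as 1 value per locus and group in 2 tables, the first for the development stages and the second for the drought groups. How the 2 libraries of a group were combined into that value is not given in the sources used here. Per the submitters' processing notes the tools were cutadapt 1.8.1, Bowtie2 2.2.9, HISAT2 2.0.5 and Cuffdiff, whose version is not given in the sources used here. The genome build and annotation are likewise not given in the sources used here. Coordinates are those of the file, which does not state whether a start counts from 0 or 1. Each table has its own set of loci, with sorghum gene identifiers as names, and 1213 named development loci and 1209 drought loci join several genes. Such joined loci cannot be split among their genes, and a fragment shared by close copies of a gene cannot be placed from these values. Since FPKM keep no read totals, the depth per sample is unknown, and no interval or detection limit from depth is given. The sums of FPKM per group, from 664672 at floral initiation to 914773 at booting, are not depths.

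The development table has 34755 loci, of which 2003 have no gene name and stay out of the comparisons. The drought table has 32726 entries. In it 20 names occur more than once, each time with the same values and coordinates, and the 21 repeated entries were used once. The tables share 32042 names, of which 26830 have the same coordinates in both. The 7 value columns are all group values, and 0 columns belong to other samples.

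Tests of groups across the 14 libraries with limma, and competitive tests of gene lists, had been fixed before the data were examined. They could not be used, because the file holds 1 value per group and so no spread between libraries. In their place the change of a locus is the difference of log2(FPKM + 1) between 2 groups, with no test. Loci enter a comparison if they have a gene name and reach 1 FPKM in at least 1 group of the table. For a comparison across the tables they must be named in both tables and reach 1 FPKM in any of the 7 groups. Loci that differ by at least 1 on this scale are counted, a threshold taken from an alternative fixed before the data were examined. The counts therefore say how many of the deposited values differ by that size and not how many would pass a test. An exact 0 may be a failed estimate, because some of the most abundant loci are at 0 in single groups, so such loci are said to be listed at 0 and no fold is given for them.

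Loci to be named were chosen by a rule fixed before the data were examined. With product names it would have taken up to 6 genes in each direction. The files hold identifiers alone, and the reference table used for names, of the assembly NCBIv3, matched 0 of them, so the rule's fallback of 2 identifiers in each direction applied. These were the 2 with the highest and the 2 with the lowest change per comparison among loci of a single gene that were not listed at 0 in either group. The limits to loci of a single gene and to loci not listed at 0 were not part of the fixed rule. The 24 gene lists defined by product names, which include markers of other tissues, could not be formed and were not tested. A further 7 loci were fixed at the same time by identifier, with recalled names that were not checked against an annotation. For the brown midrib and dwarfing lists of 3 loci each, the median change was placed among 10000 random lists of the same size, each member drawn from the 200 loci nearest in mean log2(FPKM + 1). This placement was not part of the plan fixed before the data were examined, which had these loci described and not tested. Members were drawn independently. If the loci of a list move together, its percentiles look more extreme than they should. Percentiles of comparisons that share a group, such as booting, are not independent of each other.

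Each count was recomputed with offsets of 0.1 and 5, without a minimum and with a minimum of 5 FPKM, with median-of-ratios scaling and with quantile normalization. Chosen after the data were seen were counts without loci listed at 0, of loci of a single gene, of loci with the same coordinates in both tables, with the trend over 20 classes of locus span removed, and at a difference of at least 2 on the log2 scale. The counting step was tested on copies of the values of 1 group, with 50 loci changed per fold and no spread added. The shares that passed therefore follow from the offset, the threshold and the FPKM of the loci drawn. They do not measure sensitivity in real data. For the milky stage against booting, on 16523 loci, 100% of loci changed 4-fold, 94% of those changed to 0.25 times, 72% of those changed 2.2-fold and 0% of those changed 1.5-fold passed the threshold. For D3 against D1, on 16152 loci, the shares were 100%, 88%, 76% and 0%. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.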

Results

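Gene expression was measured by RNA sequencing in the middle stem internode of ICSV12012, a variety of sweet sorghum (Sorghum bicolor), a cereal whose stem stores sugar. The 14 libraries fall into 7 groups of 2. Plants of 4 development groups grew in a field soil bed and were sampled at floral initiation, booting, the milky stage and soft dough. Plants of 3 drought groups grew in pots, had water withheld from the flag leaf stage and were harvested at booting at a soil moisture of about 13% (D1), 7% (D2) or 2% (D3). The authors' values are FPKM (fragments scaled to transcript length and to the size of the library), with 1 value per locus and group. No replicate values were given, so none of the differences below has a replicate check, and no p-value, standard deviation or n belongs to any of them. The sequencing depth is unknown, because FPKM keep no read totals.

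The development table named 32752 loci and the drought table named 32705 after repeated entries were taken once. Between 15745 (milky stage) and 16779 (floral initiation) named loci reached 1 FPKM in a development group, and between 16058 (D3) and 16312 (D2) in a drought group. Across the loci of the development table that reached 1 FPKM in some stage, the milky stage and soft dough had the most similar ranks (Spearman's rho 0.925), and floral initiation and the milky stage the least similar (0.784). In the drought table rho was 0.958 between D1 and D2, 0.945 between D2 and D3 and 0.934 between D1 and D3. These are correlations across genes, which are not independent replicates, and the tables were quantified separately, so values set across them carry that difference as well.

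**Figure D1:**
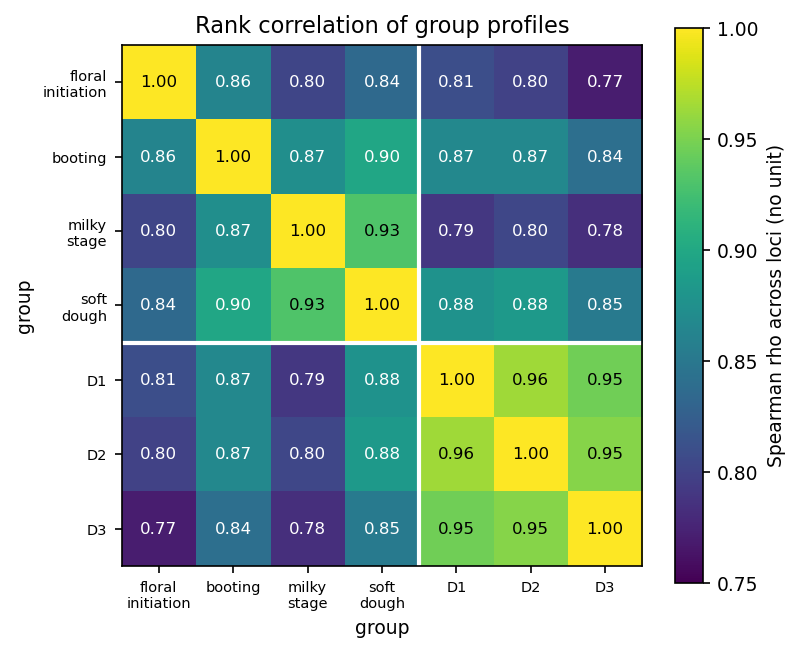
Spearman's rho (no unit) between the log2(FPKM + 1) profiles of each pair of the 7 groups, on both axes, across the 18492 loci named in both tables that reached 1 FPKM in some group. The 3 drought groups D1 to D3, below and to the right of the white lines, had rho of 0.95 to 0.96 with each other and 0.77 to 0.88 with the development groups.

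Changes are given as differences of log2(FPKM + 1), and loci are counted where this difference is at least 1, that is 2-fold with the offset. The offset makes the changes of low loci smaller than their FPKM ratios. The files pair the loci with sorghum gene identifiers and not with product names, so the loci with the widest differences appear by identifier. In addition 7 loci were fixed before the data were examined, with names recalled from published sorghum genetics. The files do not give these names, and they were not checked against an annotation. They are the brown midrib loci Sobic.004G071000 (cinnamyl alcohol dehydrogenase), Sobic.007G047300 (caffeic acid O-methyltransferase) and Sobic.004G062500 (4-coumarate:CoA ligase), whose enzymes make lignin precursors, the dwarfing loci Sobic.009G229800 (Dw1), Sobic.006G067700 (Dw2) and Sobic.007G163800 (Dw3), which set internode length, and Sobic.006G147400, a NAC transcription factor locus linked to dry stalks.

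**Figure D2:**
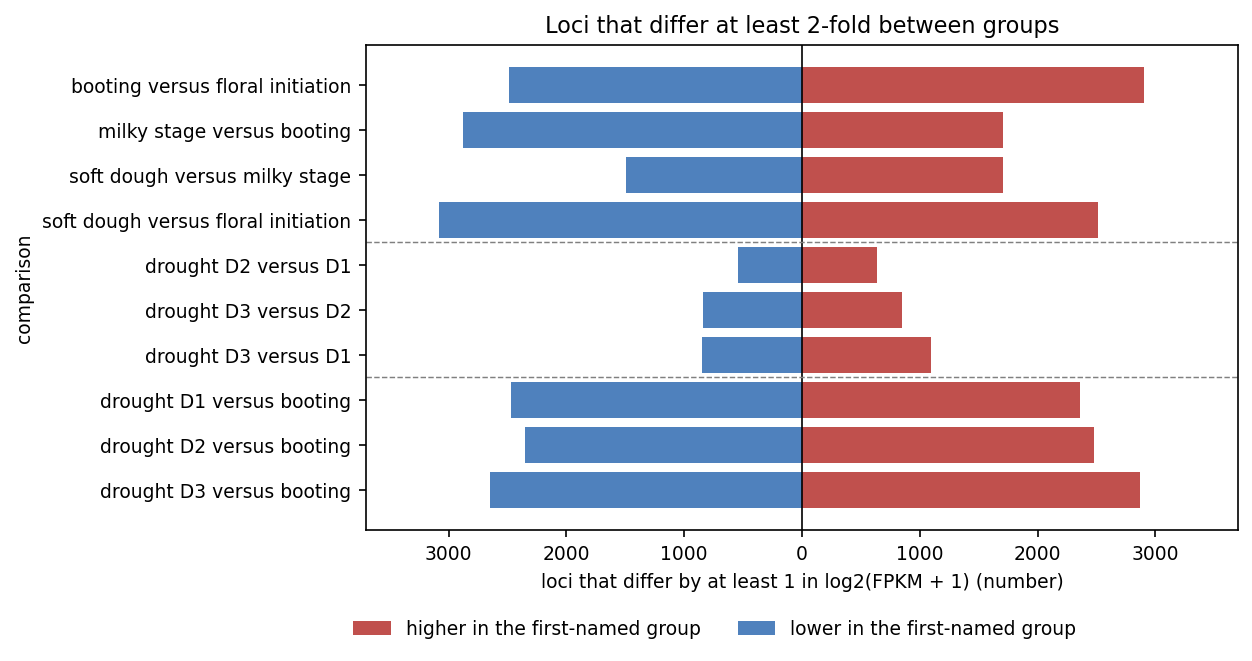
Number of loci (horizontal axis, counted from 0 in both directions) that differed by at least 1 in log2(FPKM + 1) in each of the 10 comparisons (vertical axis), with loci higher in the first-named group in red to the right and lower loci in blue to the left. Dashed lines separate comparisons of stages, of drought groups and of drought groups against booting. The bars are longest for soft dough against floral initiation, with 2515 loci higher and 3080 lower, and shortest for D2 against D1, with 633 higher and 539 lower.

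The step from floral initiation to booting asks how the internode differs between the start of head formation and the time when the head lies in the flag leaf sheath. Sobic.003G356500 (chromosome 3, 67487967 to 67492096) stood at 354 FPKM at booting and 1.68 at floral initiation, a log2 change of 7.05. Sobic.003G039400 (chromosome 3, 3695195 to 3696666) stood at 310 and 1.36 FPKM (7.04). In the other direction, Sobic.001G444500 (chromosome 1, 72145901 to 72148205) was at 1.86 FPKM at booting against 181 (-5.99) and Sobic.005G046700 (chromosome 5, 4444213 to 4445054) at 0.133 against 45.2 (-5.35). Among the brown midrib loci, caffeic acid O-methyltransferase was at 1248 FPKM at booting and 697 at floral initiation, 4-coumarate:CoA ligase at 208 and 272, and cinnamyl alcohol dehydrogenase at 126 and 110. None of these reached 2-fold. Quantile normalization moved the methyltransferase from 0.84 to 0.10, took the ligase past 2-fold (-1.03) and turned the sign for the dehydrogenase (-0.26). The list's median change of 0.20 lay at percentile 17.3 of 10000 random lists of the same size matched on mean expression, which describes these libraries alone, and it was -0.26 with quantile normalization. Placement among random lists was not in the plan fixed before the data were examined, here and in the comparisons below. Dw1 was at 7.78 FPKM at booting and 16.1 at floral initiation, Dw2 at 18.0 and 17.9, and Dw3 at 7.64 and 11.8. Dw1 passed 2-fold with an offset of 0.1 alone among the settings tried (-1.04). Of 18367 loci compared, 5385 (29.3%) differed at least 2-fold, 2899 higher and 2486 lower at booting. With an offset of 5 in place of 1, 3064 did.

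From booting to the milky stage, when the grain begins to fill, more loci were lower than higher. Sobic.002G322200 (chromosome 2, 69355902 to 69364093) was at 74.1 FPKM at the milky stage and 0.0293 at booting (6.19), and Sobic.009G245000 (chromosome 9, 58073717 to 58079719) at 1516 and 28.8 FPKM (5.67). Sobic.004G128400 (chromosome 4, 16208595 to 16210069) was at 0.025 FPKM against 89.5 at booting (-6.46), and Sobic.003G217632 (chromosome 3, 55308083 to 55311807) at 0.465 against 117 (-6.33). Of the 3 brown midrib loci, 2 were at least 2-fold lower at the milky stage. Caffeic acid O-methyltransferase was at 314 FPKM (3.97 times lower) and cinnamyl alcohol dehydrogenase at 42.5 (2.97 times lower), while 4-coumarate:CoA ligase was at 168 FPKM (1.24 times lower), and these signs were the same under both scalings tried. The median change of the list, -1.55, lay at percentile 1.93 of the random lists. Dw2 was at 9.89 FPKM, 1.82 times lower than at booting, and Dw3 at 5.11. In all, 4580 loci (24.9%) differed at least 2-fold, 1702 higher and 2878 lower. Short loci had lower changes than long ones here (rho of change with locus span 0.28 across genes), and quantile normalization moved the median change of all loci from -0.03 to 0.09 and the share of higher loci from 37.2% to 45.2%.

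Between the milky stage and soft dough fewer loci differed in total than in the earlier steps. Sobic.004G128400, which was at 0.025 FPKM at the milky stage, was at 33.1 at soft dough (5.06). Sobic.008G182700 (chromosome 8, 61621295 to 61622128) was at 22.03 FPKM against 0.0634 (4.44), and is listed at 0 at floral initiation and booting. Sobic.009G244900 (chromosome 9, 58064778 to 58069498) was at 8.72 FPKM against 322 at the milky stage (-5.06), and Sobic.004G303500 (chromosome 4, 64242735 to 64243340) at 0.235 against 31.0 (-4.70). Of the brown midrib loci 4-coumarate:CoA ligase was 2.85 times lower at soft dough, at 58.8 FPKM, while cinnamyl alcohol dehydrogenase (49.5 FPKM) and caffeic acid O-methyltransferase (379 FPKM) were 1.17 and 1.21 times higher, with the same signs under both scalings. The list's median of 0.22 lay at percentile 67.4 of the random lists. Dw3 was at 2.00 FPKM, 2.55 times lower, a change that passes 2-fold on the log2(FPKM + 1) scale (-1.02) and not with an offset of 5 (-0.53). In total 3198 loci (17.4%) differed at least 2-fold, 1705 higher and 1493 lower. At an offset of 5 the count was 1581 and lower loci were the more frequent, 764 higher and 817 lower.

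Over the whole series, soft dough against floral initiation, Sobic.003G039400 was again among the loci with the widest difference, at 418 against 1.36 FPKM (7.47), and Sobic.009G245000 was at 588 against 3.26 (7.11). Sobic.006G154500 (chromosome 6, 51423541 to 51424842) was at 0.551 against 278 FPKM (-7.49), and Sobic.001G444500 at 0.208 against 181 (-7.23). At soft dough 4-coumarate:CoA ligase was 4.62 times lower than at floral initiation and cinnamyl alcohol dehydrogenase 2.21 times lower. Caffeic acid O-methyltransferase was 1.84 times lower (-0.88), and passed 2-fold with quantile normalization alone among the settings tried (-1.15). The list's median of -1.13 lay at percentile 1.79. Dw3 was 5.87 times lower, the widest difference among the dwarfing loci, against 1.51 times lower for Dw1 and 1.15 times lower for Dw2. The dry stalk locus stayed between 0.0245 and 0.120 FPKM in the 4 stages. At least 2-fold differences were found for 5595 loci (30.5%), 2515 higher and 3080 lower, and 11328 loci (61.7%) differed at least 2-fold between some pair of the 4 stages.

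Where a locus was at least 2-fold above or below all 3 other stages, floral initiation was most often the stage that stood apart. There 1400 loci had their highest value and 1076 their lowest, against 653 and 211 at booting, 477 and 645 at the milky stage and 179 and 219 at soft dough. These numbers at an offset of 5 were 731 and 668, 342 and 66, 264 and 259, and 76 and 80, so that the order at the milky stage turned. With an offset of 0.1, 464 loci were lowest at booting and 1228 at the milky stage, and soft dough had 315 highest and 489 lowest. After quantile normalization the order at soft dough turned (204 and 201). A higher value at every step, with at least 2-fold in total, was found for 557 loci and a lower value at every step for 775. Which of these was more frequent depended on the scaling, with 707 and 692 after quantile normalization, and an offset of 5 gave 352 and 447. Dw3 and 4-coumarate:CoA ligase are among the loci with a lower value at every step.

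**Figure D3:**
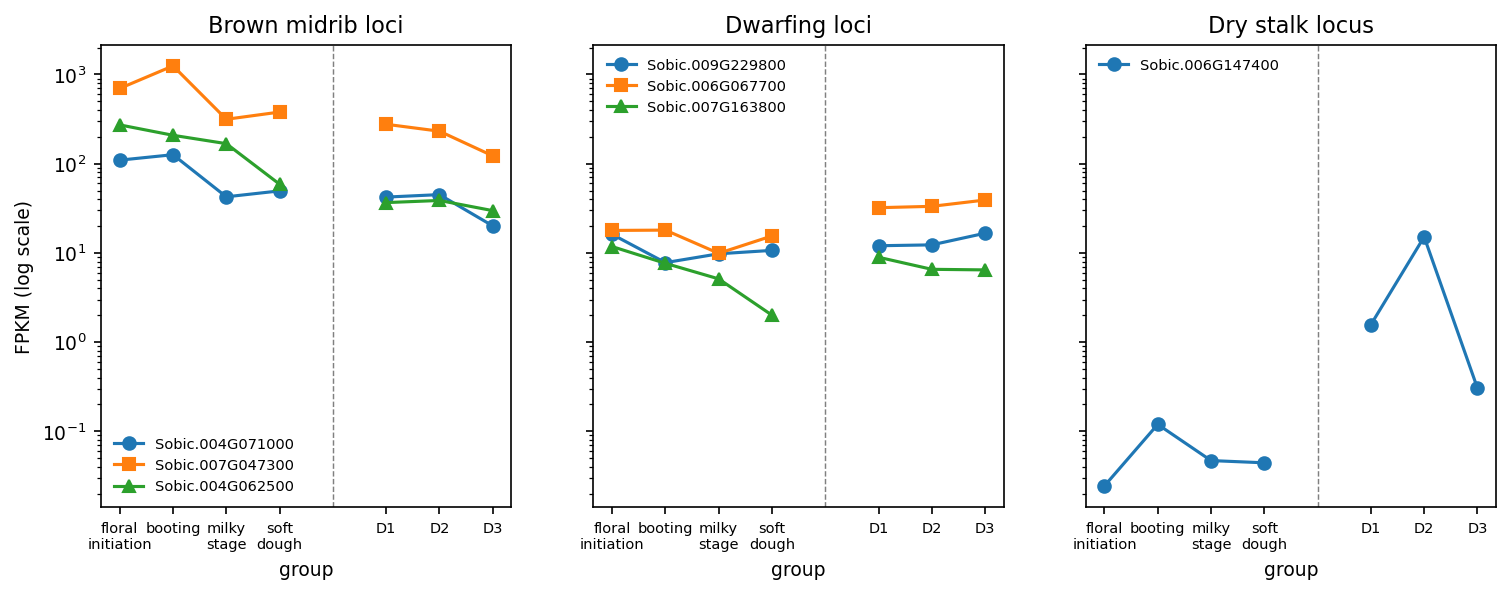
FPKM on a log axis (vertical) of the 3 brown midrib, 3 dwarfing and 1 dry stalk loci in the 7 groups (horizontal), with points for the authors' group values and lines joining groups within a table. Dashed lines separate the development from the drought table, which were quantified separately. Caffeic acid O-methyltransferase (Sobic.007G047300) goes from 1248 FPKM at booting to 122 in D3, and the dry stalk locus (Sobic.006G147400) from 1.57 in D1 to 15.1 in D2.

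The drought groups ask how the internode differs as the soil dries. From D1 to D2, Sobic.003G085300 (chromosome 3, 7351048 to 7362566) was at 335 FPKM against 3.73 (6.15) and Sobic.002G324000 (chromosome 2, 69488428 to 69490758) at 80.2 against 1.798 (4.86). Sobic.003G142900 (chromosome 3, 14189073 to 14190183) was at 0.514 FPKM against 145 (-6.59) and Sobic.004G303500 at 0.548 against 133 (-6.43). The dry stalk locus was at 15.1 FPKM in D2 and 1.57 in D1, a log2 change of 2.65. The brown midrib and dwarfing loci all differed by less than 2-fold, the widest being Dw3 at 6.55 against 8.94 FPKM (-0.40). The brown midrib median of 0.08 lay at percentile 78.0. Of 17229 loci compared, 1172 (6.80%) differed at least 2-fold, 633 higher and 539 lower in D2. The count moved to 445 with an offset of 5 and to 1909 with an offset of 0.1.

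From D2 to D3, Sobic.005G085500 (chromosome 5, 11674692 to 11792416) was at 117 FPKM against 0.0245 (6.85). It spans 117724 bases in the drought table and is listed at 0 in D1 and in all 4 stages. Sobic.007G137700 (chromosome 7, 56571472 to 56573346) was at 110 FPKM against 2.71 (4.91). Sobic.009G236400 (chromosome 9, 57513306 to 57515626) was at 0.129 against 115 FPKM (-6.68), and Sobic.009G246000 (chromosome 9, 58162911 to 58165468) at 0.0158 against 32.9 (-5.06). The dry stalk locus was at 0.305 FPKM in D3, a log2 change of -3.63 from D2. Cinnamyl alcohol dehydrogenase was at 20.1 FPKM against 45.0 (-1.13, or -0.99 with an offset of 5) and caffeic acid O-methyltransferase at 122 against 231 (-0.91, or -1.14 with quantile normalization), while 4-coumarate:CoA ligase was at 29.8 against 38.7 (-0.37). The median of the brown midrib list lay at percentile 0.13 of the random lists. In this step 1683 loci (9.77%) differed at least 2-fold, 846 higher and 837 lower. Which direction was the more frequent depended on the setting, with 423 higher and 297 lower at an offset of 5 (720 in all), 1199 and 1372 at an offset of 0.1 (2571 in all), 818 and 859 with median-of-ratios scaling, 816 and 821 with quantile normalization and 760 and 922 with the length trend removed.

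Over the whole drying series, D3 against D1, Sobic.002G324000 was at 427 FPKM against 1.798 (7.26) and Sobic.003G088400 (chromosome 3, 7689355 to 7690085) at 128 against 0.233 (6.70). Sobic.004G303500 was at 0.0452 FPKM against 133 (-7.00) and Sobic.003G142900 at 0.443 against 145 (-6.66). The 3 brown midrib loci were lower in D3, caffeic acid O-methyltransferase by 2.26 times, cinnamyl alcohol dehydrogenase by 2.10 times and 4-coumarate:CoA ligase by 1.23 times, with the same signs under both scalings. Their median of -1.04 lay at percentile 0.06 of the random lists, whose members were drawn independently. With an offset of 5 the dehydrogenase no longer reached 2-fold (-0.91). Dw1 was at 16.6 against 12.03 FPKM, Dw2 at 39.1 against 32.1 and Dw3 at 6.45 against 8.94, and their median of 0.28 lay at percentile 85.3. Of the loci compared 1943 (11.3%) differed at least 2-fold, 1097 higher and 846 lower, or 884 with an offset of 5. Some pair of the 3 drought groups differed at least 2-fold for 3003 loci (17.4%).

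D3 was the drought group that stood apart most often. In D3 563 loci were at least 2-fold above both other groups and 325 below, against 287 and 274 in D1 and 226 and 120 in D2. With an offset of 5 the order of the lowest turned, with 97 loci lowest in D3 and 110 in D1, while 281 were highest in D3 and 102 in D1. At an offset of 0.1, 671 were lowest in D3 and 501 in D1, where 462 were highest. Lowest loci thus outnumbered highest ones in D1 at either offset, and also with a minimum of 5 FPKM (214 and 207). D2 had 419 highest and 263 lowest at an offset of 0.1, 79 and 47 at an offset of 5, and 148 and 111 with that minimum. Sobic.009G236400, Sobic.009G246000 and the dry stalk locus belong to those highest in D2. A higher value at each drying step, with at least 2-fold in total, was found for 777 loci and a lower value for 554, or 419 and 230 with an offset of 5.

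Booting plants of the soil bed are the watered group of the stage at which the drought groups were harvested. They did not grow in pots, so pot and drought cannot be told apart in these comparisons, and the tables were quantified separately. In D1 Sobic.001G086800 (chromosome 1, 6729583 to 6731483) was at 480 FPKM against 1.84 at booting (7.41) and Sobic.004G340300 (chromosome 4, 67209417 to 67213650) at 113 against 0.0589 (6.74). Sobic.001G183401 (chromosome 1, 15585219 to 15588224) was at 0.0241 against 125 FPKM (-6.94) and Sobic.006G149400 (chromosome 6, 51090459 to 51095701) at 1.15 against 258 (-6.91). The 3 brown midrib loci were each at least 2-fold lower in D1 than at booting, with 42.2 FPKM for cinnamyl alcohol dehydrogenase, 276 for caffeic acid O-methyltransferase and 36.6 for 4-coumarate:CoA ligase, and a median of -2.17 at percentile 0.28, or -1.55 with quantile normalization. Of 18492 loci named in both tables, 4832 (26.1%) differed at least 2-fold, 2362 higher and 2470 lower in D1, or 2562 with an offset of 5.

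In D2, still against booting and across separately quantified tables, Sobic.009G119200 (chromosome 9, 46821033 to 46826334) was at 853 against 1.83 FPKM (8.24) and Sobic.002G367000 (chromosome 2, 72661801 to 72663352) at 319 against 1.87 (6.80). Sobic.001G377300 (chromosome 1, 66558369 to 66562398 in the development table, with another end in the drought table) was at 7.54 against 1157 FPKM (-7.08) and Sobic.002G109400 (chromosome 2, 13300630 to 13301496) at 2.32 against 346 (-6.71). The brown midrib median of -2.40 (-1.80 with quantile normalization) lay at percentile 0.03, with all 3 loci at least 2-fold lower. The dry stalk locus was at 15.1 FPKM against 0.120 at booting (3.85). In all 4825 loci (26.1%) differed at least 2-fold, 2476 higher and 2349 lower. This order turned with an offset of 5, with 1189 higher and 1347 lower (2536 in all), with median-of-ratios scaling (2314 and 2438), with the length trend removed (2277 and 2293), at a difference of at least 2 on the log2 scale (461 and 618) and among loci with the same coordinates in both tables (1722 and 1877).

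In D3 Sobic.009G119200 was at 945 FPKM against 1.83 at booting (8.38) and Sobic.003G397400 (chromosome 3, 70714984 to 70715693) at 5562 against 16.9 (8.28). Across the drought groups the latter was at 762, 1453 and 5562 FPKM. Sobic.002G072200 (chromosome 2, 7347191 to 7348612) was at 0.187 against 441 FPKM (-8.54) and Sobic.007G223600 (chromosome 7, 65105672 to 65107929) at 0.0379 against 119 (-6.86). The brown midrib loci were lower than at booting by 10.2 times for caffeic acid O-methyltransferase, 6.99 times for 4-coumarate:CoA ligase and 6.28 times for cinnamyl alcohol dehydrogenase, with a median of -2.76 at percentile 0.05. Of the dwarfing loci Dw2 was at 39.1 against 18.0 FPKM (2.17 times higher) and Dw1 at 16.6 against 7.78 (2.14 times higher). Both passed 2-fold on the log2(FPKM + 1) scale, and neither did with quantile normalization (0.88 and 0.81) or an offset of 5 (0.94 and 0.76), nor Dw1 with median-of-ratios scaling (0.96). Dw3 was at 6.45 against 7.64 FPKM, and the median of the dwarfing list lay at percentile 90.4. Over the 10 comparisons the percentiles of the dwarfing list ranged from 15.4 to 90.4. A difference of at least 2-fold was found for 5515 loci (29.8%), 2870 higher and 2645 lower in D3, or 3073 with an offset of 5. The order turned among loci with the same coordinates in both tables (2035 higher and 2125 lower), at a difference of at least 2 on the log2 scale (698 and 771), and by small margins with median-of-ratios scaling (2708 and 2725), quantile normalization (2597 and 2616), an offset of 0.1 (3650 and 3666) and the length trend removed (2623 and 2670). Loci longer in the drought table were shifted upwards against booting by 0.27 to 0.30 more than loci with the same coordinates, and 10 of the 11 identifiers named against booting have the same coordinates in both tables. Of the 7 fixed loci 4 have other coordinates in the drought table, where Dw1 and Dw3 are longer and caffeic acid O-methyltransferase and the dry stalk locus shorter, and the shift of the longer loci exceeds the margin by which Dw1 passed 2-fold.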

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

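All tests in this part were chosen after the data had been seen. Of the 2003 development loci without a gene name, 1084 reached 1 FPKM in at least 1 stage, a signal in data the comparisons do not use. Of them 302 reached 10 FPKM. Between 745 (soft dough) and 801 (booting) reached 1 FPKM in a given stage, and they held 1.30% to 1.76% of the summed FPKM.

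Some of the most abundant loci are listed at exactly 0 in a group. Sobic.001G141300 was at 16363, 0, 4737 and 14043 FPKM from floral initiation to soft dough and between 19774 and 20318 in the drought groups. Sobic.002G324200 was at 4397, 15565, 0 and 0 FPKM from floral initiation to soft dough. It was at 12085 and 14660 FPKM in D1 and D2 and at 0 in D3. Joined loci of several genes are among the abundant loci listed at 0 as well. Counted once per locus over both tables, 3.41% of the 176 loci reaching 1000 FPKM have a 0 in some group (exact 95% interval 1.26 to 7.27), against 0.288% (0.116 to 0.593) of those reaching 100 to 1000 FPKM, which argues against silence of the genes as the whole account. A failed estimate stays open, since 6 of the 176 loci have a 0 and 1 has a lowest value above 0 and below 1, against 7 and 52 in the class of 100 to 1000 FPKM. Cuffdiff, named in the processing notes, can skip loci with very many fragments, which may be the step behind some of these zeros, and for any single locus silence is not excluded.

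Loci that are longer in the drought table than in the development table had higher drought values. The median change from booting of these 2215 loci lay above that of the 14175 loci with the same coordinates by 0.29 in D1, 0.30 in D2 and 0.27 in D3, and by 0.06 to 0.10 in the other 3 stages. The 2094 loci that are shorter in the drought table had no matching shift downwards (differences of 0.0071, 0.015 and -0.030). FPKM are scaled to transcript length, so a shorter gene model need not lower them. The shorter loci therefore cannot decide whether gene models that differ between the tables have an effect. The cause for the longer loci stays open. Loci with other coordinates are not the whole source of the differences between D3 and booting, since 29.3% of the loci with the same coordinates differed at least 2-fold. The same outer coordinates need not mean the same gene model. Gene models, pot, drought and separate quantification stay open for the loci with the same coordinates and were not told apart.

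Short loci were higher at booting than in every other group. The change from booting went with locus span in each of the 6 other groups (Spearman's rho across genes 0.16 to 0.33), while over the 15 pairs of groups without booting rho lay between -0.09 and 0.10. A length trend as the whole cause of the differences between the milky stage and booting is argued against, because 3555 of the 4580 loci also differed at least 2-fold, with the same sign, after its removal (4213 in all). The drought groups, also harvested at booting, did not share the trend. They cannot decide whether the stage is its source, because pot, drought and separate quantification also set them apart from booting. Their rho against booting was 0.21 in D1, 0.23 in D2 and 0.19 in D3. Against the milky stage and soft dough it lay between -0.09 and -0.04, while these stages had 0.28 and 0.33 against booting. The sets of loci differ, since drought groups were set against stages over 14175 loci and stages against each other over 18367. Handling of the booting libraries that depends on length, such as RNA quality or fragment size, stays open. The stage, pot, drought and separate quantification stay open as well and were not told apart from such handling.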

How the results depend on the processing

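The difference of at least 2 on the log2 scale, loci without a 0, loci of a single gene, the same coordinates in both tables and the removed length trend were chosen after the data were seen. Of 121 recomputed counts, 95 lay within 1.5 times the reported count. The 26 others came from the offset or the threshold, which set by construction how many loci pass. With an offset of 0.1, D2 against D1 gave 1909 loci and D3 against D2 2571. With an offset of 5 the counts were 3064 (booting against floral initiation), 2319 (milky stage against booting), 1581 (soft dough against milky stage), 3134 (soft dough against floral initiation), 445 (D2 against D1), 720 (D3 against D2), 884 (D3 against D1), 2562, 2536 and 3073 (D1, D2 and D3 against booting), 6623 (any of the 4 stages) and 1333 (any of the 3 drought groups). At a difference of at least 2 they were, in the same order, 1265, 1168, 421, 1585, 201, 282, 396, 1088, 1079, 1469, 3591 and 596. Leaving out the minimum cannot change a count, since a difference of 1 needs 1 FPKM, so the counts of that setting are among the 95 by construction. Of 440 values of identifiers and fixed loci, 426 kept their side of 2-fold, 9 lost it, 5 gained it and 0 past it turned their sign. The identifiers were picked for the widest changes and could hardly have lost 2-fold, so the 426 overstate how stable a typical locus is. Among the 70 changes of fixed loci, 4, each under 2-fold, had another sign under quantile normalization. Of 108 counts of loci that stood apart in a group or moved 1 way, 28 moved by over 1.5 times. No paired analysis was possible because the columns carry no replicate values. For the same reason the alternatives without the variance trend, with the compared libraries alone, with a replicate block and without each library in turn were not run, nor were the list tests with camera or fry. The depth behind any value is unknown.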

Other observations

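All tests in this part were chosen after the results had been seen. Loci that differed in drying also differed between stages more often than random lists matched on mean expression, in several directions. Of 811 loci named in both tables and at least 2-fold lower in D3 than D1, 303 (37.4%) were also at least 2-fold lower at the milky stage than at booting (random median 126, at most 164) and 63 were higher (random median 75). From the milky stage to soft dough 181 of them were higher (random median 71, at most 108). Of 1062 loci higher in D3 than D1, 229 were lower at the milky stage than at booting (at most 205) and 166 were higher (at most 133), and 299 (28.2%) were higher at booting than at floral initiation (at most 193). The random lists were not matched on how much a locus varies. Of loci lower in D3 that differed 2-fold between booting and the milky stage, 82.8% (exact 95% interval 78.5 to 86.5) were lower at the latter. Of those higher in D3 58.0% (52.9 to 62.9) were. Among all loci that differed 2-fold in that step, 2878 of 4580 were lower. These shares cannot decide whether a link to drying exists. Loci lower in D3 were picked for a high D1 value, and D1 had ranks nearer to booting (rho 0.867) than to the milky stage (0.790). The intervals treat loci as independent. What links the loci lower in both was not tested.

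Loci beside each other along a chromosome differed the same way between booting and the milky stage more often than in shuffles. Of 17014 single-gene loci, 1037 differed at least 4-fold. In 89 adjacent pairs both loci were at least 4-fold higher or both at least 4-fold lower, while 1000 shuffles of the changes over positions gave a mean of 38.4 and at most 57, which argues against chance placement. Of these pairs 52 lay at least 5000 bases apart, against a shuffled mean of 21.3 and at most 37, so closer pairs were not the whole excess. Distance cannot decide whether shared reads are the cause, since similar copies that share reads can lie further apart. At any distance, there were 82 adjacent pairs that differed 4-fold the same way from floral initiation to booting (at most 56 in shuffles). From the milky stage to soft dough there were 13 (at most 13) and from D1 to D3 9 (at most 12). Similar neighbouring copies may account for part of the 89 pairs, which was not tested.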
